A study of Mus musculus with 8 samples.

How the data were processed

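Poly(A) RNA of anterior neural progenitor cells was sequenced in 8 libraries. The cells were derived from E14 mouse embryonic stem cells in serum-free N2B27 medium, with bFgf at first and with the WNT inhibitor Xav939 in the later days. There were 4 wild-type (WT) libraries and 4 libraries of cells lacking a poised enhancer (PE), a regulatory element that its name places 109 kb from Lhx5. The deletion was made with CRISPR-Cas9 and pairs of guide RNAs, and 2 clonal lines gave 2 null libraries each, per the labels. The labels call the samples biological replicates. Groups were taken from the sample titles and column headers. Because the null columns are numbered within a clone, each was assigned to its clone and not to a single sample title. No column of per-sample values was left unmapped.

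The FPKM values (fragments scaled by gene length and mapped total) of the 8 libraries and their mean per genotype were computed by the authors, per the file headers. The table also holds the authors' mean read count per genotype, a signal column whose scaling is not stated, and the authors' fold, which equalled the ratio of the null to the WT mean within 0.1 percent in all 26310 table entries with WT reads above 0. The deposited p-value of each gene has no stated test and no adjusted counterpart. FastQC, SAMtools, TopHat2, Cufflinks and DESeq2, and the builds GRCm38 and mm10, are named in the submitters' processing notes without versions, roles or order. Whether reads were assigned by strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty.

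Read counts per library were not analysed here, so the total depth of each library is unknown. The authors' mean reads summed to 26693189 in WT and 26864352 in null. The steps between low FPKM values gave relative depths of 0.983 to 1.19 against WT replicate 1. An FPKM of exactly 0 can be a failed estimate: 420 tested genes were listed at 0 in at least 1 library, and 10 of these had at least 100 mean reads in the authors' table. For such genes the value of each library is given in place of a mean.

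The design written before the data were examined named a count model for counts and limma for FPKM. As the table analysed holds only FPKM values per library, limma 3.58.1 in R 4.3.3 was used, with trend and robust variance moderation, on log2(FPKM + 1) of the 14521 genes with a mean FPKM of at least 1. Every log2 fold change is on that scale, which understates changes of low genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The null against WT comparison used 4 against 4 libraries in 2 groups. The clone comparisons came from a fit of 3 groups (WT, clone 1 and clone 2) that share 1 estimate of the spread per gene. That estimate holds the spread between libraries of a line and not the spread between lines. Lhx5 was also compared by an exact two-sided permutation test. Of the identifiers, 45900 had coordinates in GENCODE M21 (GRCm38), and 20570 table entries carried a gene symbol.

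A total of 26 gene lists was fixed before the data were examined. They covered forebrain transcription factors, LIM homeobox genes, midbrain and hindbrain genes, neural progenitor genes, neuronal genes, Cajal-Retzius genes, pluripotency genes, WNT antagonists, WNT targets, WNT ligands and receptors, FGF ligands and targets, Hedgehog and ventral genes, BMP and dorsal genes, neural crest, mesoderm, endoderm and surface ectoderm genes, cell cycle genes, p53 targets, immediate early and stress response genes, hypoxia and glycolysis genes, cholesterol synthesis genes, imprinted genes, Y-linked genes, Polycomb genes, and genes recalled to lie beside Lhx5. Lists with at least 3 tested members were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance without comparing it with other genes, were run beside it. Counts of members are given over all genes tested and, where stated, adjusted over the list alone.

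Genes are named by a rule fixed beforehand. Lhx5 was always named. For null against WT, the 10 highest and 10 lowest changes past the threshold were taken among genes with a standard symbol whose null libraries all lay on one side of the WT libraries. For each list, up to 4 members past the threshold were taken by smallest adjusted p, or the 1 with the smallest p if none passed. The 5 highest and 5 lowest changes between the clones and the 6 tested genes nearest Lhx5 were added. Genes past the threshold in both clones, members that passed over their list alone, Hesx1 in clone 2, and single genes outside these rules were named after their values were seen.

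Genes within 1 Mb of the Lhx5 start were examined as a set. The median log2 fold change of each chromosome was compared with 10000 random gene sets of the same size. Genes changed in both clones were counted by direction and set beside the overlap of independent lists, the correlation in 50 simulations of unchanged groups sharing the WT libraries, and fits in which each clone had its own pair of WT libraries. The alternatives were rescaling by median ratios, no filter on low values, a stricter filter, a pseudocount of 0.1, each library left out in turn, each clone alone, a mean of both clones in the 3-group fit, the libraries of a line treated as correlated, and an absolute log2 fold change of at least 1. A block on the replicate numbers of the column headers was added after the data were seen. The count-based alternatives and the block on the numbers of the sample titles were not run.

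The fits were tested on simulated data of 14521 genes, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. The simulated null against WT comparison recovered 52.2, 77.6 and 92.4 percent of them, and the simulated clone 1 against WT comparison 70.1, 95.5 and 95.5 percent. For clone 2 against clone 1 the shares were 56.7, 82.1 and 95.5 percent. Unchanged genes called were 5, 6 and 9 in the same order. The simulated noise was independent between libraries, whereas real libraries of a line were correlated (consensus correlation 0.656). For null against WT the simulation can therefore overstate recovery and understate false calls. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and the R packages statmod 1.5.0 and data.table (version 1.17.8), were also used.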

Results

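Gene expression was measured by poly(A) RNA sequencing in mouse anterior neural progenitor cells, an in vitro model of early forebrain tissue. The 4 WT libraries were compared with 4 libraries lacking the poised enhancer of Lhx5, of which 2 came from clone 1 and 2 from clone 2. Levels are in FPKM and are given as mean ± SD, with n = 4 for WT, n = 4 for null and n = 2 for each clone. FPKM values summed to between 518491 and 528726 per library, and 13983 to 14338 genes reached 1 FPKM. Pairwise correlations of log2 values across genes, which are not independent replicates, were 0.954 to 0.960 among WT libraries, 0.941 to 0.956 within a clone, 0.912 to 0.937 between the clones and 0.929 to 0.955 between null and WT.

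Clone 1 replicate 2 differed from the other libraries in its RNA composition. Genes related to ribosomal RNA made up 1.53 percent of its FPKM, against 0.138 to 0.296 percent in the others. The non-polyadenylated RNAs Rn7sk, Rpph1 and Rmrp stood at 250.2, 371 and 112 FPKM in this library, against 8.05 to 28.4, 3.02 to 22.8 and 1.03 to 7.62 FPKM elsewhere. Of 47 replication-dependent histone genes, whose messages lack a poly(A) tail, 46 were higher in clone 1 replicate 2 than in clone 1 replicate 1, with a median log2 difference of 0.92.

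The first question was whether removing the enhancer lowered Lhx5, a LIM homeodomain transcription factor of the developing forebrain (ENSMUSG00000029595, chromosome 5, 120431699 to 120441223, plus strand, GRCm38). Lhx5 fell from 16.4 ± 1.05 FPKM in WT to 1.31 ± 0.432 FPKM in null, a 12.5-fold lower level. The WT libraries stood at 16.9, 17.5, 16.2 and 15.0 FPKM, the clone 1 libraries at 1.24 and 0.854 FPKM, and the clone 2 libraries at 1.90 and 1.26 FPKM. The level was 15.7-fold lower in clone 1 and 10.4-fold lower in clone 2. In limma the log2 fold change was -2.93 (SE 0.13, adjusted p = 8.22e-05). It was -3.09 in clone 1 (adjusted p = 3.6e-06) and -2.76 in clone 2 (adjusted p = 7.23e-06), and limma gave an adjusted p = 0.0881 for the difference between the clones. The exact two-sided permutation test gave p = 0.0286, the smallest value that its 70 arrangements allow. It treats the libraries as exchangeable, although those of a line are not independent. In the authors' deposited table the mean read counts of Lhx5 were 1366 in WT and 110.2 in null, a fold of 0.0807.

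Comparing all null with all WT libraries asked which other genes differed between them. The null libraries all come from derived clones, whereas the WT libraries carry no clone label. An effect of the deletion therefore cannot be told apart from one of deriving clones. Apart from Lhx5, 1 gene was higher and 6 were lower among the 14521 genes tested. Nnat, an imprinted gene encoding neuronatin (chromosome 2, 157560078 to 157562522), rose from 46.2 ± 1.41 to 197 ± 37.3 FPKM, reaching 4.96 times the WT level in clone 1 and 3.57 times in clone 2. It lies within Blcap on the opposite strand, which was at 25.1 ± 1.47 FPKM in WT and 20.6 ± 2.14 FPKM in null. Ifitm1, an interferon-inducible transmembrane protein gene on chromosome 7, fell from 23.3 ± 1.70 to 12.5 ± 0.996 FPKM. Sgce, the imprinted epsilon-sarcoglycan gene on chromosome 6, fell from 19.4 ± 1.06 to 13.3 ± 0.432 FPKM, and Sall3, a zinc finger transcription factor gene on chromosome 18, from 11.1 ± 0.599 to 6.88 ± 0.568 FPKM. Prag1, a pseudokinase gene on chromosome 8, fell from 29.2 ± 0.982 to 18.5 ± 1.88 FPKM, and Pls3, an actin-bundling plastin gene on chromosome X, from 108 ± 1.49 to 80.6 ± 5.14 FPKM. CAAA01147332.1, a gene model on the unplaced scaffold JH584295.1, stood at 21.9, 26.9, 27.3 and 19.1 FPKM in the WT libraries and was listed at 0 in both clone 1 libraries and at 0 and 0.395 FPKM in the clone 2 libraries.

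Limma gave log2 fold changes of 2.05 for Nnat (SE 0.12, adjusted p = 0.000645), -0.85 for Ifitm1 (adjusted p = 0.0091), -0.51 for Sgce (adjusted p = 0.034), -0.62 for Sall3 (adjusted p = 0.0417), -0.64 for Prag1 (adjusted p = 0.0447), -0.42 for Pls3 (adjusted p = 0.0447) and -4.50 for CAAA01147332.1 (adjusted p = 2.08e-05). Each of these genes lay on the same side of WT in all 4 null libraries. In total 8 genes passed the threshold and 688 had an unadjusted p under 0.05. The count was 106 with the mean of both clones in the 3-group fit, whose error leaves out the spread between the clones. It was 5 after rescaling and 3 with the libraries of a line treated as correlated. It was 3 without WT replicate 1, 4 without WT replicate 2, WT replicate 4 or clone 1 replicate 2, and 5 without clone 2 replicate 1. Lhx5, Nnat and CAAA01147332.1 passed in each of these fits, whereas Sall3, Prag1 and Pls3 were lost after rescaling, with log2 fold changes of -0.60, -0.61 and -0.40 there. Sall3 and Sgce were lost without each library other than clone 1 replicate 1, Prag1 without each other than clone 2 replicate 2, and Pls3 without each other than these 2, with adjusted p-values of up to 0.294. These 4 genes were also lost without a filter on low values and, at an adjusted p = 1, with the libraries of a line treated as correlated. Ifitm1 was lost without WT replicate 1 (adjusted p = 0.058), without WT replicate 4 (adjusted p = 0.0659) and with correlated lines, and its adjusted p ran from 0.00024 to 1 over these fits. The authors' deposited p-values, adjusted here over 28134 genes with reads, passed the same threshold for 220 genes, 117 higher, 102 lower and 1 at a fold of 1, including all 8. Of these 220, 148 were among the genes tested here.

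**Figure D1:**
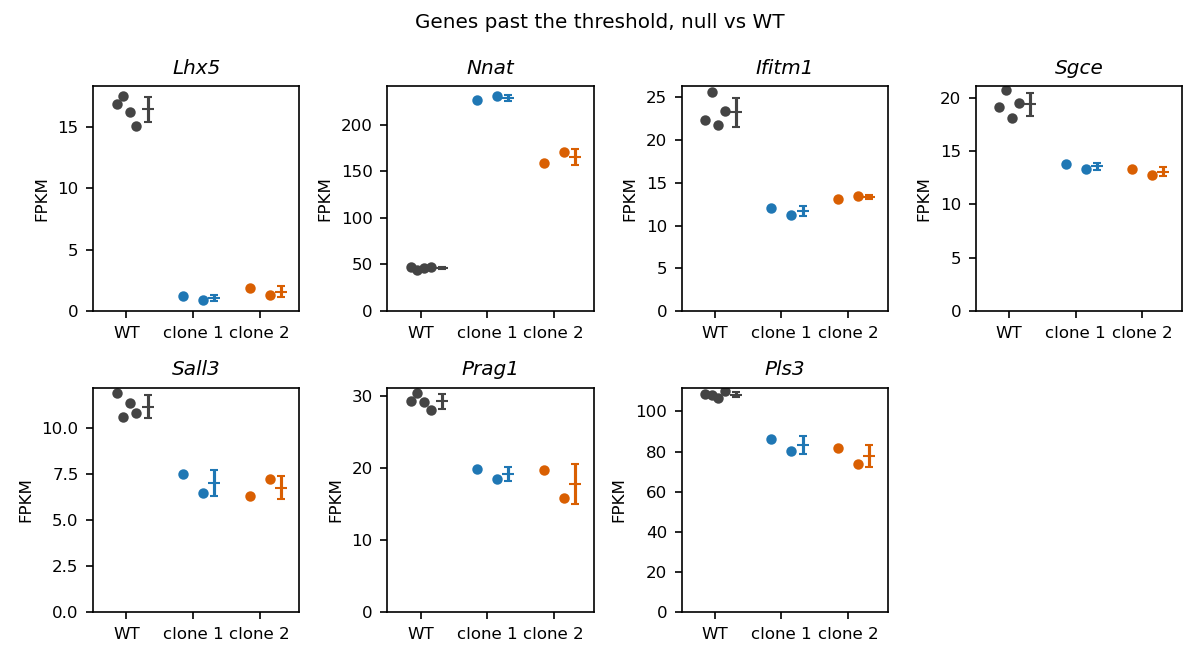
FPKM of the 7 named genes past the threshold in each of the 8 libraries, on linear axes from 0, with points for libraries and the mean ± SD of WT, clone 1 and clone 2. All 4 null libraries lay below all WT libraries for Lhx5, Ifitm1, Sgce, Sall3, Prag1 and Pls3, and above them for Nnat.

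Forebrain transcription factors tended to be lower in null against WT, although 0 of the 14 tested passed limma's test over all genes. Of 14 tested, 12 had negative log2 fold changes, with a median of -0.58 (camera adjusted p = 2.4e-05; adjusted p = 0.167 with an estimated correlation), and Lhx2, Rax and Fezf2 were lower adjusted over the list alone. Lhx2, a regulator of forebrain and eye development, was at 11.5 ± 0.922 FPKM in WT and 5.79 ± 1.58 FPKM in null (limma adjusted p = 0.27 over all genes). All 7 tested WNT antagonists had negative changes, with a median of -0.29 (camera adjusted p = 0.000102; adjusted p = 0.322 with an estimated correlation), and Sfrp1 and Frzb were lower adjusted over the list alone. The median of the WNT antagonists was -0.034 in clone 1 and -0.54 in clone 2, and that of the forebrain genes -0.24 and -0.72. Sfrp1 was at 71.3 ± 2.17 FPKM in WT, 50.8 ± 4.07 FPKM in clone 1 and 53.3 ± 5.24 FPKM in clone 2. All 9 WNT targets had positive changes, with a median of 0.089 (camera adjusted p = 0.0172; adjusted p = 0.345 with an estimated correlation), and Apcdd1 was higher adjusted over the list alone. The median of the WNT targets was -0.22 in clone 1 and 0.45 in clone 2, and -0.05 in null without clone 2 replicate 2.

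Further lists passed camera for null against WT, and several of them went opposite ways in the clones. The median was 0.37 for 10 FGF ligands and targets (camera adjusted p = 0.000209; adjusted p = 0.507 with an estimated correlation), all of them positive, but -0.30 in clone 1 and 1.22 in clone 2. It was 0.13 for 12 BMP and dorsal genes (camera adjusted p = 0.000181; adjusted p = 0.345 with an estimated correlation), with Id1 higher adjusted over the list alone, and -0.006 in clone 1 and 0.22 in clone 2. It was 0.44 for 7 surface ectoderm genes (camera adjusted p = 0.00359; adjusted p = 0.345 with an estimated correlation), with 1.40 in clone 1 and -0.33 in clone 2, and 0.20 for 12 immediate early and stress response genes (camera adjusted p = 2.85e-06; adjusted p = 0.167 with an estimated correlation). The 10 midbrain and hindbrain genes had a median of 0.18 (camera adjusted p = 0.0288; adjusted p = 0.677 with an estimated correlation), the 9 pluripotency genes 0.19 and the 16 p53 targets 0.059 (camera adjusted p = 0.0304 and adjusted p = 0.677 with an estimated correlation for each). After rescaling, these last 3 lists no longer passed. Their medians in clone 1 and clone 2 were -0.34 and 0.81, 0.77 and -0.38, and 0.44 and -0.30 in that order. In null the median was -0.014 and -0.015 for midbrain and hindbrain genes without clone 2 replicate 1 or 2, -0.097 and -0.043 for pluripotency genes without clone 1 replicate 1 or 2, and -0.046 for p53 targets without clone 1 replicate 1. It was 0 for BMP and dorsal genes without clone 2 replicate 1. Lower lists were cholesterol synthesis, with 15 of 15 genes negative and a median of -0.19 (camera adjusted p = 1.45e-06; adjusted p = 0.397 with an estimated correlation), and cell cycle, with 18 of 20 negative and a median of -0.082 (camera adjusted p = 0.00584; adjusted p = 0.345 with an estimated correlation). Their medians were -0.013 and -0.15 in clone 1 and -0.37 and -0.029 in clone 2. Of 15 hypoxia and glycolysis genes 14 were negative, with a median of -0.20 (camera adjusted p = 0.0304; adjusted p = 0.677 with an estimated correlation), but the median was 0.065 in clone 1 and -0.45 in clone 2.

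The remaining lists did not pass camera for null against WT. The camera adjusted p was 0.351 for 3 LIM homeobox genes, among which Lhx2 was lower and Lmx1b higher adjusted over the list alone. It was 0.889 for 21 neural progenitor genes, 0.468 for 11 neuronal genes, 0.928 for 4 Cajal-Retzius genes with Calb2 higher over the list alone, and 0.702 for 16 WNT ligands and receptors with Fzd1 lower and Wnt9a higher over the list alone. It was 0.468 for 8 neural crest genes with Sox9 lower over the list alone, 0.929 for 4 endoderm genes, 0.373 for 3 Y-linked genes, 0.928 for 24 Polycomb genes and 0.765 for 8 genes recalled to lie beside Lhx5. Among 22 imprinted genes (camera adjusted p = 0.316), Nnat, Zrsr1 and Snrpn were higher and Sgce and Impact lower adjusted over the list alone, and fry's test for changes in either direction gave an adjusted p = 1.78e-06. For the WNT antagonists, fry's test in either direction also passed (adjusted p = 0.00283). Only 2 Hedgehog and ventral genes and 1 mesoderm gene were tested, and none of them passed limma's test. Median, mean and camera direction differed in sign for LIM homeobox, neural progenitor, WNT ligand and receptor, and imprinted genes. Over all genes, Nnat and Sgce were the list members past limma's threshold. With an estimated correlation 0 of the 24 lists passed camera, with 3 at an unadjusted p under 0.05, and 0 passed fry's one-direction test, with 4 at an unadjusted p under 0.05.

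**Figure D2:**
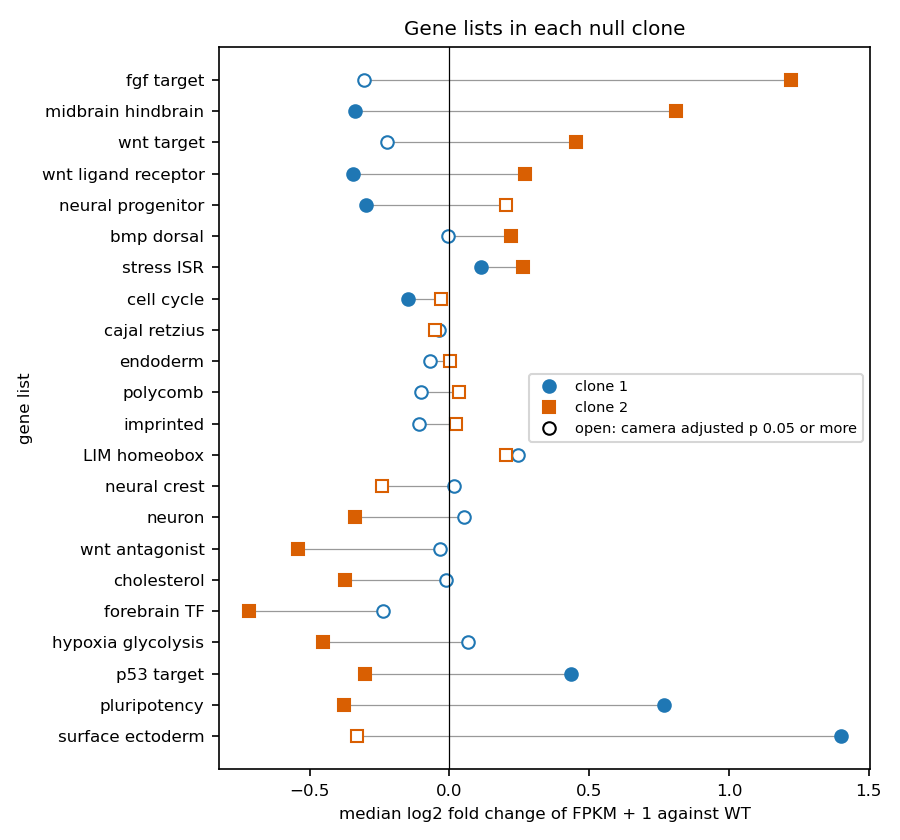
Median log2 fold change against WT of 22 gene lists, on the x axis, for clone 1 (circles) and clone 2 (squares), with filled symbols where camera's adjusted p was under 0.05. Midbrain and hindbrain genes lay at -0.34 in clone 1 and 0.81 in clone 2, and pluripotency genes at 0.77 and -0.38.

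Genes around Lhx5 other than Lhx5 itself were examined next. Distances were taken from the Lhx5 start and not from the enhancer, whose coordinates were not used here. Within 1 Mb of the Lhx5 start, 17 of 62 annotated genes were tested and 0 passed limma's test, whether adjusted over all genes or over the list alone, with 0 at an unadjusted p under 0.05. The 6 nearest were Sdsl at 26.5 kb, Plbd2 at 51.6 kb, Slc8b1 at 79.5 kb, Tpcn1 at 102.5 kb, Rita1 at 162.6 kb and Ddx54 at 181 kb from Lhx5. Their log2 fold changes were -0.16, 0.011, -0.14, -0.067, -0.072 and 0.004 in that order. These 6 all lie on the same side of Lhx5. Rbm19, on the other side at 232.7 kb, had a log2 fold change of 0.017. The name of the element carries a minus sign before its distance. Read as upstream of Lhx5, which is on the plus strand, it would place the element on the side of Rbm19. Against WT, Dtx1, a Notch pathway ubiquitin ligase gene 248.5 kb away, was 0.96 higher on the log2 scale in clone 1 (limma adjusted p = 0.0126) and fell by 0.67 in clone 2 (limma adjusted p = 0.0394).

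Clonal stem cell lines can gain or lose chromosomes, so the median change of each chromosome was compared with random gene sets. In null against WT the medians of chromosome 3 (relative to all genes -0.012, adjusted p = 0.0126 from the random sets) and chromosome 17 (0.011, adjusted p = 0.0378) passed. In clone 1 there were 7 chromosomes past the threshold, of which Y had the farthest median (0.26, adjusted p = 0.0042 from the random sets). The others lay between -0.028 for X and 0.026 for chromosome 17. In clone 2 there were 0, with 4 at an unadjusted p under 0.05. Y did not pass there (-0.165, adjusted p = 0.0766 from the random sets), although Ddx3y, Eif2s3y and Uty stood at 0.67 to 2.9 percent of WT. Random gene sets do not measure the spread between libraries or lines.

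One stretch of chromosome 4 was lower in clone 2 than in WT along its length. From Rab2a to Epha7 (chromosome 4, 8535644 to 28967499), 45 of 46 tested protein-coding genes had negative log2 fold changes and 39 passed limma's test as lower. Their median was -0.59, a linear ratio of 0.663 on FPKM + 1, against 0.001 for the other 721 protein-coding genes of chromosome 4. In clone 1 the same genes had a median of 0.17, with 38 positive. This stretch was noticed after the values were seen.

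**Figure D3:**
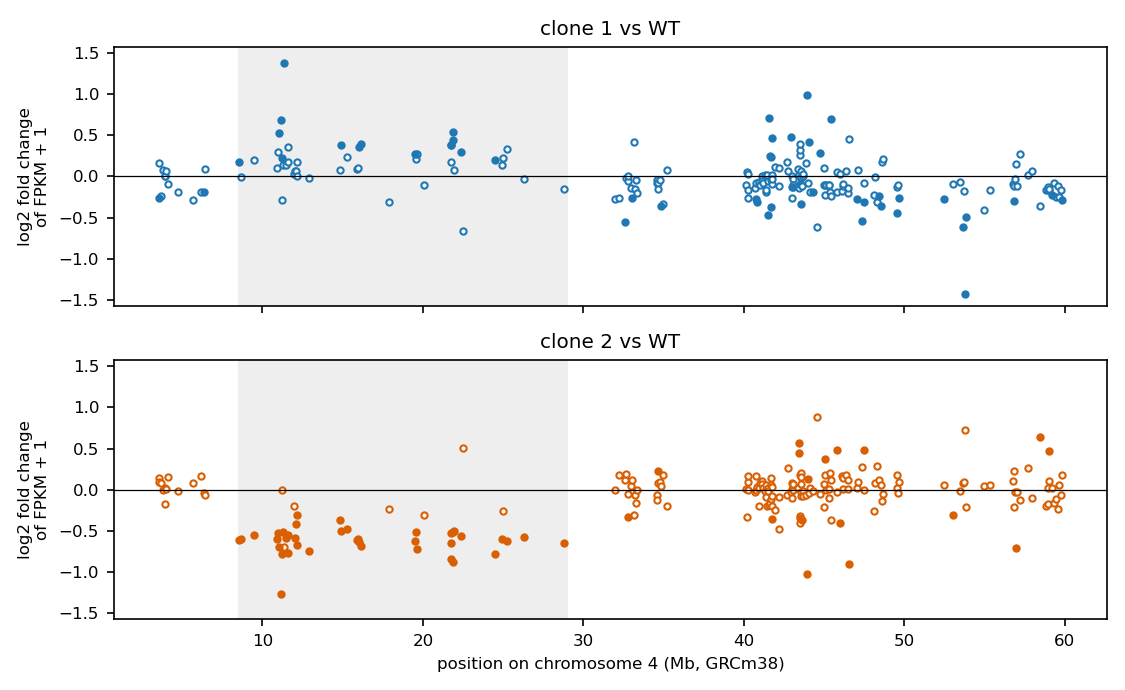
Log2 fold change against WT (y axes) of clone 1 (top) and clone 2 (bottom) for 211 protein-coding genes along the first 60 Mb of chromosome 4 (x axis, Mb), with filled points at an adjusted p under 0.05 and a grey band from 8.54 to 28.97 Mb. In the band 45 of 46 genes lay below 0 in clone 2, with a median of -0.59.

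Clone 1 was compared with WT to see what each independently derived line showed. Its cells had higher pluripotency, epithelial and p53 target transcripts and lower levels of several progenitor and regional genes. Of 9 pluripotency genes 7 rose, with a median log2 fold change of 0.77 (camera adjusted p = 1.45e-07; adjusted p = 0.388 with an estimated correlation). Among them Dnmt3b, a de novo DNA methyltransferase gene, went from 75.3 ± 4.58 to 110.2 ± 8.87 FPKM, Dppa4 from 2.64 ± 0.279 to 6.39 ± 0.997 FPKM and Fgf5, an epiblast growth factor gene, from 1.95 ± 0.672 to 4.81 ± 0.595 FPKM. Among 7 surface ectoderm and epithelial genes 4 rose and 1 fell, with a median of 1.40 (camera adjusted p = 0.000486; adjusted p = 0.388 with an estimated correlation). Cdh1, encoding E-cadherin, rose from 7.39 ± 1.79 to 22.2 ± 3.39 FPKM and Cldn6, a tight junction gene, from 2.95 ± 0.679 to 9.35 ± 0.533 FPKM. Of 16 p53 targets 12 rose, with a median of 0.44 (camera adjusted p = 1.76e-10; adjusted p = 0.388 with an estimated correlation), including Plk2 from 6.20 ± 1.03 to 15.8 ± 2.31 FPKM, Mdm2 from 32.9 ± 0.950 to 40.9 ± 2.33 FPKM and Bbc3, which encodes the death factor PUMA, from 28.1 ± 4.37 to 44.5 ± 2.37 FPKM.

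Among lower groups in clone 1, 10 of 21 neural progenitor genes fell and 1 rose, with a median of -0.30 (camera adjusted p = 0.0332; adjusted p = 0.618 with an estimated correlation). Sox21 fell from 43.1 ± 4.70 to 22.4 ± 0.138 FPKM, Sox1 from 21.8 ± 0.860 to 14.6 ± 0.213 FPKM and Cdh2, encoding N-cadherin, from 61.8 ± 5.91 to 39.4 ± 2.70 FPKM. Of 10 midbrain and hindbrain genes 3 fell, with a median of -0.34 (camera adjusted p = 0.0288; adjusted p = 0.657 with an estimated correlation). These were Wnt1, from 98.1 ± 8.81 to 47.2 ± 5.32 FPKM, En1, from 32.3 ± 4.63 to 19.5 ± 1.35 FPKM, and Gbx2, from 1.5 ± 0.424 to 0.167 ± 0.0130 FPKM. Of 16 WNT ligands and receptors 9 fell, with a median of -0.34 (camera adjusted p = 0.0332; adjusted p = 0.388 with an estimated correlation), among them Wnt3a and Fzd1. Of 20 cell cycle genes 8 fell, with a median of -0.15 (camera adjusted p = 0.0288; adjusted p = 0.453 with an estimated correlation), such as Pcna from 219.9 ± 5.95 to 179 ± 2.28 FPKM, and this list no longer passed after rescaling. The 12 stress response genes had a median of 0.11 (camera adjusted p = 0.0194; adjusted p = 0.614 with an estimated correlation), with Egr1 higher and Hspa5 lower. The 3 Y-linked genes rose, with a median of 1.08 (camera adjusted p = 5.15e-06; adjusted p = 0.388 with an estimated correlation).

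Other lists did not pass camera in clone 1, though some members passed limma's test. Genes that fell among 14 forebrain transcription factors (camera adjusted p = 0.123) included Sp8, Lhx2 and Otx1. Dll3, Gap43 and Neurog2 rose among 11 neuronal genes (0.101), and Cxcr4 fell among 4 Cajal-Retzius genes (0.841). Sfrp1 and Frzb fell among 7 WNT antagonists (0.841), Dusp6 fell among 10 FGF genes (0.255), and 2 of 9 WNT targets rose and 3 fell (0.893). Msx1 rose and Id3 and Msx3 fell among 12 BMP and dorsal genes (0.71), while Twist1 and Ets1 rose among 8 neural crest genes and those that fell included Sox9 (0.644). Ptch1 and Nkx6-1, the 2 Hedgehog and ventral genes tested, and Pdgfra, the 1 mesoderm gene, fell. Among 22 imprinted genes 7 rose and 8 fell (0.893), with Grb10 at 76.6 ± 0.990 FPKM in WT and 12.3 ± 3.36 FPKM in clone 1 and Mest at 295 ± 23.2 and 134 ± 8.85 FPKM. Counts of higher and lower members were 1 and 1 of 3 LIM homeobox genes (0.434), 1 and 5 of 24 Polycomb genes (0.644), 1 and 0 of 15 hypoxia genes (0.0546), 1 and 0 of 8 recalled Lhx5 neighbours (0.312), and 0 and 0 for 15 cholesterol genes (0.81) and 4 endoderm genes (0.841). Median, mean and camera direction differed in sign for LIM homeobox, BMP and dorsal, cholesterol, imprinted and neighbour genes.

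In total 2266 genes passed in clone 1 against WT, 604 higher and 1662 lower (73.3 percent lower), and after rescaling 1942 passed, 882 higher and 1060 lower (54.6 percent lower). The count was 443 without clone 1 replicate 2, the library with the high share of non-polyadenylated RNA, and 992 to 1074 without WT replicate 1, 3 or 4. Of 85 genes named for this comparison, 41 no longer passed without clone 1 replicate 2, including Sox1, Cdh2, En1, Gbx2, Fgf5, Bbc3 and Lhx2. Without clone 1 replicate 1, the midbrain and hindbrain, neural progenitor, WNT ligand and stress response lists no longer passed camera. With an estimated correlation 0 of 24 lists passed camera, with 1 at an unadjusted p under 0.05, and 9 passed by fry.

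Clone 2 had higher midbrain and hindbrain, FGF and WNT transcripts than WT and lower forebrain, neuronal and cholesterol synthesis transcripts. Wnt1, En1 and Gbx2, which fell in clone 1, rose here. Of 10 midbrain and hindbrain genes 8 rose, with a median log2 fold change of 0.81 (camera adjusted p = 7.66e-07; adjusted p = 0.253 with an estimated correlation). Wnt1 and En1, markers of the midbrain-hindbrain border region, reached 171 ± 9.09 and 68.2 ± 7.89 FPKM, and Gbx2, a hindbrain determinant, rose from 1.5 ± 0.424 to 7.23 ± 1.34 FPKM. Of 10 FGF ligands and targets 9 rose, with a median of 1.22 (camera adjusted p = 7.94e-08; adjusted p = 0.253 with an estimated correlation), including the feedback inhibitor genes Dusp6, from 3.35 ± 0.683 to 12.8 ± 4.16 FPKM, and Spry2, from 3.96 ± 0.684 to 16.0 ± 6.33 FPKM. Of 9 WNT targets 6 rose, with a median of 0.45 (camera adjusted p = 0.00174; adjusted p = 0.253 with an estimated correlation), such as Apcdd1 from 23.2 ± 0.5 to 43.4 ± 4.13 FPKM and Axin2 from 40.4 ± 2.80 to 55.6 ± 3.08 FPKM. Of 16 WNT ligands and receptors 8 rose and 3 fell, with a median of 0.27 (camera adjusted p = 0.00343; adjusted p = 0.253 with an estimated correlation), and Wnt3a reached 10.3 ± 1.01 FPKM from 3.48 ± 0.777 FPKM. Of 12 BMP and dorsal genes 5 rose, with a median of 0.22 (camera adjusted p = 0.000759; adjusted p = 0.253 with an estimated correlation), among them Id1, Id2, Id3 and Msx3.

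Of 14 forebrain transcription factors 7 fell in clone 2, with a median of -0.72 (camera adjusted p = 0.00105; adjusted p = 0.287 with an estimated correlation). Pax6 fell from 38.6 ± 1.68 to 14.5 ± 4.78 FPKM, the eye field gene Rax from 7.18 ± 1.18 to 1.41 ± 1.05 FPKM, Fezf1 from 35.7 ± 0.771 to 19.9 ± 5.70 FPKM and Otx2 from 206.5 ± 10.8 to 166 ± 10.5 FPKM. Of 7 WNT antagonists 4 fell, with a median of -0.54 (camera adjusted p = 4.23e-05; adjusted p = 0.253 with an estimated correlation), including Frzb from 19.3 ± 0.5 to 12.1 ± 0.993 FPKM. Of 11 neuronal genes 5 fell, with a median of -0.34 (camera adjusted p = 0.00497; adjusted p = 0.253 with an estimated correlation), such as Gap43 and Stmn2, and 3 of 9 pluripotency genes fell, Dppa5a, Dnmt3b and Nanog, with a median of -0.38 (camera adjusted p = 0.00497; adjusted p = 0.406 with an estimated correlation). Of 15 cholesterol synthesis genes 13 fell, with a median of -0.37 (camera adjusted p = 1.32e-10; adjusted p = 0.253 with an estimated correlation), including Hmgcs1 from 343 ± 20.2 to 238 ± 21.4 FPKM and Dhcr7 from 88.1 ± 3.30 to 61.0 ± 3.64 FPKM. Of 16 p53 targets 7 fell, with a median of -0.30 (camera adjusted p = 5.88e-05; adjusted p = 0.388 with an estimated correlation), among them Trp53inp1, which lies in the lower stretch of chromosome 4. Of 15 hypoxia and glycolysis genes 3 fell, Slc2a1, Pfkl and Ndrg1, with a median of -0.45 (camera adjusted p = 1.93e-05; adjusted p = 0.388 with an estimated correlation). Of 12 stress response genes 5 rose, with a median of 0.26 (camera adjusted p = 0.0145; adjusted p = 0.388 with an estimated correlation). The 3 Y-linked genes fell, with a median of -2.65 (camera adjusted p = 7.94e-08; adjusted p = 0.253 with an estimated correlation).

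Lists that did not pass camera in clone 2 again held members past limma's test. Of 21 neural progenitor genes 8 rose and 1 fell (camera adjusted p = 0.058), with Zic1 going from 1.91 ± 0.610 to 9.49 ± 2.25 FPKM and Fabp7 from 2.03 ± 0.664 to 14.0 ± 6.81 FPKM. Of 22 imprinted genes 8 rose and 2 fell (0.112). Lmx1b rose and Lhx2 fell among 3 LIM homeobox genes (0.53), Pax3 rose and Sox9 fell among 8 neural crest genes (0.0962), and Bub1 and Ccnb2 fell among 20 cell cycle genes (0.53). Single genes rose among Cajal-Retzius (Calb2, 0.985), endoderm (Lama1, 0.77) and surface ectoderm genes (Eya1, 0.77), while 2 of 24 Polycomb genes rose and 3 fell (0.646) and 1 of 8 recalled Lhx5 neighbours fell (0.112). The Hedgehog and mesoderm genes tested did not pass. Median, mean and camera direction differed in sign for LIM homeobox, Cajal-Retzius and Polycomb genes.

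In total 2036 genes passed in clone 2 against WT, 1025 higher and 1011 lower. The count was 174 without clone 2 replicate 2, 765 without WT replicate 4, 1101 without WT replicate 3, 1294 without WT replicate 2 and 1160 without a filter on low values. Of 92 genes named for this comparison, 55 no longer passed without clone 2 replicate 2, including Wnt1, En1, Axin2, Sfrp1, Otx2 and Nanog, while Gbx2, Dusp6, Spry2, Pax6, Rax, Fezf1, Frzb and Apcdd1 still passed. With an estimated correlation 0 of 24 lists passed camera, with 3 at an unadjusted p under 0.05, and 16 passed by fry.

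Genes changed in both clones were compared to ask what the lines shared. In both, 78 genes passed in the same direction, 22 higher and 56 lower, and 645 passed in opposite directions. Shared higher genes included Nnat, Gpx3, a secreted glutathione peroxidase gene at 45.8 ± 5.95 FPKM in WT, 152.5 ± 33.2 FPKM in clone 1 and 78.9 ± 0.634 FPKM in clone 2, and Rspo1, a secreted enhancer of WNT signalling at 18.1 ± 2.57, 25.7 ± 0.771 and 28.1 ± 2.16 FPKM. Apcdd1, Lmx1b, Nfe2l2, Zrsr1 and Snrpn were also among them. Shared lower genes included Lhx5, Lhx2, Ifitm1, Sall3, Prag1, Sgce, Col1a2 and Thbs1, a matricellular glycoprotein gene at 84.4 ± 6.25 FPKM in WT, 30.4 ± 4.77 FPKM in clone 1 and 57.5 ± 3.06 FPKM in clone 2. Raxos1, a transcript antisense to Rax, stood at 3.55 ± 0.549, 1.48 ± 0.0933 and 0.734 ± 0.536 FPKM. Independent lists would share 158.3 genes, 42.6 higher and 115.7 lower, and hold 159.4 in opposite directions.

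The correlation of the fold changes of the clones across genes was 0.0861, against a mean of 0.315 in simulations without any effect, and the covariance was 0.0154 against 0.0379, a difference of -0.0224. The simulations gave all libraries the same noise per gene. The clone 1 libraries correlated at 0.941 and the WT libraries at 0.954 to 0.960. The simulated noise of WT, and with it both simulated values, can therefore be too high. With WT replicates 1 and 2 for clone 1 and the other WT libraries for clone 2, 12 genes were shared, where independent lists would give 2.1, and 23 were opposite, where they would give 2.23. With the WT pairs exchanged 16 were shared, where independent lists would give 19.4, and 169 were opposite, where they would give 19.2. The correlations in these fits were -0.054 and -0.11. The count of shared genes was 131 without clone 1 replicate 1, and 26 to 37 without clone 1 replicate 2, clone 2 replicate 2 or WT replicate 1, 3 or 4.

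**Figure D4:**
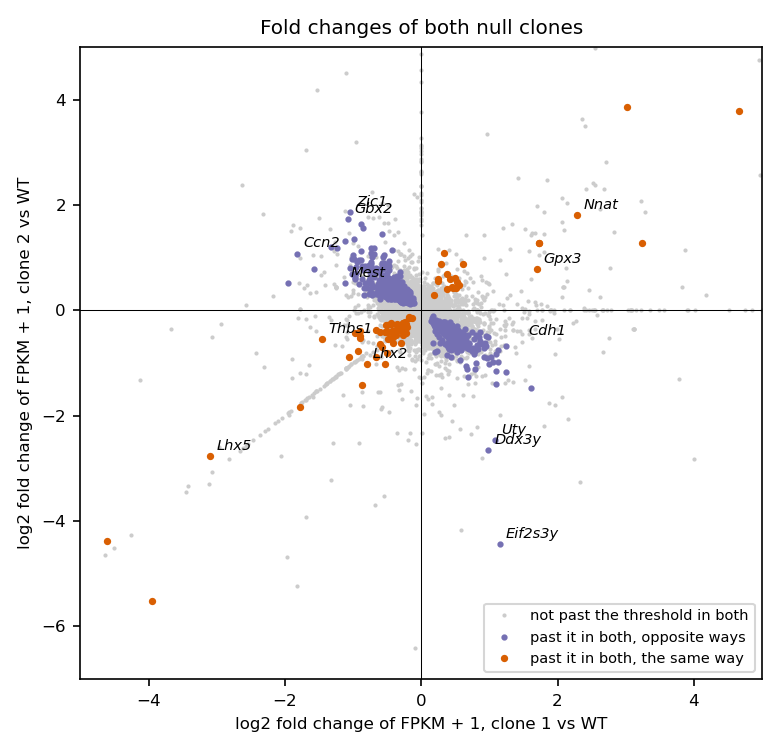
Log2 fold change against WT of each tested gene in clone 1 (x axis) and clone 2 (y axis), with 78 genes past the threshold in the same direction in orange, 645 in opposite directions in purple and the rest in grey. Lhx5 and Nnat lay far from 0 on both axes, and 13 genes lay outside the axes.

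The clones of the same genotype were compared directly to see how far these lines differ, and they differed in more genes than either differed from WT. The calls rest on the spread between libraries of a line. A difference of culture run was not tested apart from that of the line. The differences included regional, signalling, pluripotency, p53 target and Y-linked genes. All 10 midbrain and hindbrain genes were higher in clone 2, with a median of 1.252 (camera adjusted p = 8.4e-05; adjusted p = 0.4 with an estimated correlation), and Gbx2 was at 0.167 ± 0.0130 FPKM in clone 1 and 7.23 ± 1.34 FPKM in clone 2. Of 10 FGF genes 9 were higher, with a median of 1.496 (camera adjusted p = 0.000126; adjusted p = 0.4 with an estimated correlation), of 16 WNT ligands and receptors 8 were higher and 1 lower, with a median of 0.46 (camera adjusted p = 0.0016; adjusted p = 0.371 with an estimated correlation), and of 21 neural progenitor genes 14 were higher and 2 lower, with a median of 0.28 (camera adjusted p = 0.0179; adjusted p = 0.4 with an estimated correlation). All 9 pluripotency genes were lower in clone 2, with a median of -1.01 (camera adjusted p = 3.28e-06; adjusted p = 0.4 with an estimated correlation), including Nanog at 8.09 ± 0.867 FPKM in clone 1 and 2.02 ± 0.411 FPKM in clone 2. Of 16 p53 targets 14 were lower, with a median of -0.70 (camera adjusted p = 4.6e-08; adjusted p = 0.4 with an estimated correlation), such as Trp53inp1 at 90.8 ± 16.2 and 22.5 ± 2.58 FPKM.

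Of 11 neuronal genes 6 were lower in clone 2, with a median of -0.30 (camera adjusted p = 0.0179; adjusted p = 0.4 with an estimated correlation), and the proneural gene Neurog2 was at 11.2 ± 1.55 FPKM in clone 1 and 0.901 ± 0.565 FPKM in clone 2. Lower lists also included WNT antagonists, with 5 of 7 lower and a median of -0.36 (camera adjusted p = 0.0169; adjusted p = 0.4 with an estimated correlation), surface ectoderm genes, with 4 of 7 lower and 1 higher and a median of -1.28 (camera adjusted p = 0.0169; adjusted p = 0.4 with an estimated correlation), and hypoxia genes, with 8 of 15 lower and a median of -0.54 (camera adjusted p = 0.000126; adjusted p = 0.451 with an estimated correlation). Of 15 cholesterol genes 12 were lower, with a median of -0.37 (camera adjusted p = 3.28e-06; adjusted p = 0.4 with an estimated correlation). The 3 Y-linked genes were lower, with a median of -3.63 (camera adjusted p = 4.39e-06; adjusted p = 0.371 with an estimated correlation), and Eif2s3y was at 24.3 ± 0.930 FPKM in WT, 55.4 ± 7.13 FPKM in clone 1 and 0.162 ± 0.0304 FPKM in clone 2.

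Lists that did not pass camera between the clones were forebrain transcription factors, with 4 higher and 7 lower of 14 (camera adjusted p = 0.137), WNT targets, with 6 higher and 1 lower of 9 (0.0626), BMP and dorsal genes, with 5 higher and 1 lower of 12 (0.146), and neural crest genes, with 2 higher and 3 lower of 8 (0.137). Pax6 was at 31.2 ± 1.32 FPKM in clone 1 and 14.5 ± 4.78 FPKM in clone 2, and Hesx1, an anterior neural plate gene, at 33.5 ± 4.17 and 4.41 ± 2.80 FPKM. Among 22 imprinted genes 10 were higher and 6 lower (0.75), among 24 Polycomb genes 10 were higher and 3 lower (0.639), among 20 cell cycle genes 8 were higher and 3 lower (0.265), and among 12 stress response genes 3 were higher and 3 lower (0.937). Cxcr4 among Cajal-Retzius genes (0.75), Lmx1b among LIM homeobox genes (0.838) and Lama1 among endoderm genes (0.817) were higher, 3 of 8 recalled Lhx5 neighbours were lower (0.137), and the 2 Hedgehog genes and 1 mesoderm gene tested were higher. Median, mean and camera direction differed in sign for LIM homeobox and stress response genes.

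Over all genes, the highest changes in clone 2 against clone 1 included Car3, a carbonic anhydrase gene at 0.414 ± 0.05 FPKM in clone 1 and 10.8 ± 5.12 FPKM in clone 2, Ccn2, at 1.24 ± 0.154 and 15.6 ± 0.102 FPKM, and the neural progenitor list members Fabp7 and Zic1. The Y-linked list members Eif2s3y and Ddx3y were among the lowest. The other genes of that rule were listed at 0 in some libraries. Snora28 was listed at 0 in both clone 1 libraries and at 27 and 35.8 FPKM in clone 2, with WT libraries at 0, 7.20, 8.73 and 17.1 FPKM. Mir92-2 was at 138.4 and 138.3 FPKM in clone 1 and listed at 0 in the other 6 libraries, and Mir1957b was at 31.2 and 21.5 FPKM in clone 1 and listed at 0 in clone 2, with WT libraries at 24.8, 27.3, 11.1 and 10.9 FPKM. The authors' deposited table gave mean reads of 66.7 in WT and 74.8 in null for Snora28, 40.7 and 39.9 for Mir92-2, and 0 and 0 for Mir1957b. Ktn1 was listed at 0 in both clone 2 libraries and stood at 84.9 and 72.8 FPKM in clone 1 and 80.4 to 86.7 FPKM in WT, while that table gave mean reads of 9269 in WT and 8874 in null. In total 5794 genes passed limma's test between the clones, 3618 higher and 2176 lower in clone 2, and 3098 passed without clone 2 replicate 2. With an estimated correlation 0 of 24 lists passed camera, with 2 at an unadjusted p under 0.05, and 18 passed by fry.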

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

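The tests used to weigh explanations in this part were chosen after the results were seen, apart from the counts over other splits of the libraries. Among 78 groups of 4 libraries searched for a library far from the others, 2 were found, and chance gives about 1 in 20 groups, or 3.9 here. Sesn1, a p53 target gene, stood at 13.1 FPKM in WT replicate 2 and at 11.7 to 11.8 FPKM in the other WT libraries. Genes related to ribosomal RNA made up 1.53 percent of FPKM in clone 1 replicate 2 and 0.138 to 0.214 percent in the other null libraries.

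Of the 36 genes that the naming rule gave for null against WT, 13 differed between the clones by limma's test, while 39.9 percent of all tested genes did. For each of these 13 genes both libraries of one clone lay above both of the other. As log2 differences of clone 2 minus clone 1, the lower ones were Nnat (-0.47, adjusted p = 0.000443), Utf1 (-0.51, adjusted p = 0.0111), Sesn1 (-0.33, adjusted p = 0.012), Egr1 (-0.48, adjusted p = 0.0371), Slc8b1 (-0.57, adjusted p = 0.0125), Ddx54 (-0.18, adjusted p = 0.0362) and Eif2s3y (-5.60, adjusted p = 3.77e-09). The higher ones were Pax8 (0.90, adjusted p = 0.00386), Vim (0.26, adjusted p = 0.0113), Apcdd1 (0.58, adjusted p = 0.00055), Nkx6-1 (0.28, adjusted p = 0.0373), Pdgfra (0.87, adjusted p = 0.00038) and Mcm6 (0.12, adjusted p = 0.0332).

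Of 24 gene lists, 12 differed between the clones by camera with the preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. The median differences of clone 2 minus clone 1 were 1.252 for midbrain and hindbrain, 0.28 for neural progenitor, 0.46 for WNT ligand and receptor and 1.496 for FGF genes. They were -0.30 for neuronal, -1.01 for pluripotency, -0.36 for WNT antagonist, -1.28 for surface ectoderm, -0.70 for p53 target, -0.54 for hypoxia, -0.37 for cholesterol and -3.63 for Y-linked genes.

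Gm23935, annotated as a microRNA gene, had mean reads of 9154 in null and 4413 in WT in the authors' deposited table, while its FPKM was listed at 0 in all 8 libraries.

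In clone 2, 45 of the 46 protein-coding genes from Rab2a to Epha7 on chromosome 4 lay below WT, with a median of -0.59, while in clone 1 the median was 0.17, with 38 positive. A scaling of whole libraries would lower the rest of the chromosome as well, and the median there was 0.001, which argues against it. A single factor shared by the stretch, as a loss of a copy gives, would spread the fold changes no more widely than elsewhere, and their median absolute deviation was 0.72 times that of the other genes of the chromosome. A copy loss in this line is therefore a candidate explanation, found and tested on the same data. The ratio to WT was 0.663 on FPKM + 1, above the 0.5 of 1 lost copy of 2 in every cell. That scale understates changes of low genes, so the comparison with 0.5 does not decide. No DNA was measured here. The clone, which is the group in the design that sets these libraries apart, stays open as an untested biological difference.

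Of the genes past the threshold in clone 1, 73.3 percent were lower than in WT. After rescaling, with a factor of 0.952 for clone 1 replicate 2 and 1.002 to 1.026 for the other libraries, 54.6 percent were lower. Because rescaling centres the fold changes, this test does not decide, and the scaling of the libraries cannot be told apart from a change of the cells. RNA without a poly(A) tail in that library stays open, since histone genes were 0.92 higher there than in clone 1 replicate 1 on the log2 scale, for 46 of 47 genes, and without it the count was 443, of which 60.3 percent were lower. A difference of the clone itself was not tested apart from these.

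Among 22 imprinted genes the median size of the null against WT log2 fold change was 0.30, against 0.052 in 10000 lists matched on expression. That is percentile 100, so the expression level of these genes is argued against. Between the clones the median size was 0.48 against 0.18 in matched lists, again percentile 100, so variation between clones of one genotype stays open. An effect shared by both clones cannot be told apart from it, since of the 7 imprinted genes past the threshold in both clones 4 went the same way, namely Nnat, Sgce, Snrpn and Zrsr1, and 3 went opposite ways, and both comparisons share the WT libraries. By Fisher's exact test, imprinted genes were more often called than other genes in null against WT (2 of 22, p = 6.1e-05, where Sgce was lost when any one of 7 libraries was left out, without a filter and with correlated lines) and between the clones (16 of 22, p = 0.00344). This test was chosen after the calls were seen, so its p-values lend no independent support.

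Of the 35 splits of the 8 libraries into 4 and 4, 1 split gave as many genes as the real one, which was the real split itself with 8 genes, and the highest other count was 3. For gene lists 1 of the 35 splits, again the real one with 13 lists, gave as many, and the highest other count was 11. In each case 1 of 35 is the smallest share that these splits can give. Chance can be excluded by these counts only if the libraries are exchangeable, and libraries of the same line were correlated (consensus correlation 0.656), so it is not excluded for the lines. With the lines as correlated blocks 3 of the genes passed. The 6 splits that put the clones in different groups gave 0 to 2 genes and 8 to 11 lists, and with an estimated correlation 0 lists passed camera, with 3 at an unadjusted p under 0.05.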

How the results depend on the processing

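The alternatives chosen after the data were seen were the removal of genes listed at 0, the removal of chromosome Y and the start of chromosome 4, the authors' p-values, the leaving out of libraries for gene lists, the rescaled and estimated-correlation list tests of the clone comparisons, the chromosome medians of single clones, the block on column numbers and, for genes shared by the clones, all except the separate WT pairs. The planned block on title numbers was not run, because the null columns are numbered 1 and 2 within each clone and cannot be assigned to titles numbered 1 to 4. Column numbers did not pair the libraries, since same-numbered libraries deviated from their group means with correlations of -0.085 to 0.022. With these numbers as a replicate block, which leaves WT replicates 3 and 4 no weight, 1 gene passed for null against WT, 36 in clone 1, 45 in clone 2, 2995 between the clones and 8 in both clones, and Lhx5, at -2.99, did not pass (adjusted p = 0.0886, against 1.22e-06 to 0.005 under the other alternatives). The count-based DESeq2 and voom alternatives were not run, since the table analysed holds no counts per library. Where leaving out a library left 1 in a clone, that library was assumed to vary like the others. The depth of each library is unknown, so what depth limits could not be computed.

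Lhx5 kept its direction under every alternative and passed under each other than that block, from -3.04 to -2.83 with libraries left out and at -3.59 with a pseudocount of 0.1. For null against WT, 8 genes passed. The count was 5 after rescaling, 3 with the libraries of a line as correlated blocks (consensus correlation 0.656), 3 at an absolute log2 fold change of at least 1, 106 with the mean of both clones in the 3-group fit, and 220 (148 of them tested here) by the authors' p-values. It was 3 to 12 with libraries left out, of which 3 to 7 were shared with the 8. Clone 1 only gave 2045 and clone 2 only 2404, where the spread between clones is absent by construction. It is likewise left out of the error of the 3-group fit that gave 106. Within 1 Mb of Lhx5 the count of 0 became 1 for clone 1 only and 1 for clone 2 only.

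Without a filter on low values, 1506 genes passed in clone 1, 1160 in clone 2 and 47 in both clones. An absolute log2 fold change of at least 1 left 88 in clone 1, 102 in clone 2 and 505 between the clones, where a fit of those 2 groups alone gave 3674. With libraries left out the counts ran from 443 to 3111 in clone 1, 174 to 2406 in clone 2, 3098 to 5910 between the clones and 26 to 131 in both clones. The lowest counts came without clone 1 replicate 2 in clone 1 and without clone 2 replicate 2 in the other 3. Separate pairs of WT libraries gave 12 and 16 genes in both clones, a comparison first made with separate fits and changed once those values were seen. Without chromosome Y and chromosome 4 before 30 Mb the counts were 2238, 1953 and 5736 in clone 1, clone 2 and between the clones. Rescaling moved the median log2 fold change from -0.048 to -0.006 in clone 1.

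With an estimated correlation, 0 gene lists passed camera in null against WT, 0 in clone 1, 0 in clone 2 and 0 between the clones, and the counts at an unadjusted p under 0.05 were 3, 1, 3 and 2. The lists of clone 1 numbered 5 to 11 with libraries left out, and 5 came without clone 1 replicate 1. Chromosome medians past the threshold were 2 for null against WT, 7 for clone 1 only and 0 for clone 2 only, where 4 had an unadjusted p under 0.05.

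Against the direction in all null libraries, clone 1 only gave 1.15 for Eif2s3y and medians of -0.006 for BMP and dorsal, -0.30 for FGF, 0.065 for hypoxia, -0.34 for midbrain and hindbrain, -0.22 for WNT target and 1.08 for Y-linked genes. Clone 2 only gave -0.30 for p53 target, -0.38 for pluripotency, -0.33 for surface ectoderm and 0.27 for WNT ligand and receptor genes. With libraries left out, medians ran from 0 to 0.16 for BMP and dorsal, -0.015 to 0.45 for midbrain and hindbrain, -0.046 to 0.19 for p53 target, -0.097 to 0.39 for pluripotency and -0.05 to 0.19 for WNT target genes. Of 5602 values of genes and lists compared, 69 changed sign, 18 of them past the threshold in at least 1 of the fits, and these 18 were counted as reversed by a rule narrowed after the values were seen. Of the values of named genes, 650 of 747 kept their side of the threshold without such a reversal for null against WT, 978 of 1190 for clone 1, 1093 of 1288 for clone 2 and 1226 of 1273 between the clones. A change of sign where neither fit passed was not counted against these values, so the counts do not measure kept direction. The cause was not tested where none is given.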

Other observations

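The genes, regions and tests in this part were chosen after the results were seen. Of the 7 imprinted genes past the threshold in both clones, 3 moved in opposite ways and 4 the same way. Nnat, Snrpn and Zrsr1 rose in both clones and Sgce fell in both. In clone 1 the maternally expressed RNAs of the Dlk1 domain on chromosome 12 rose, with Meg3 going from 142 ± 5.83 to 217.8 ± 8.96 FPKM (log2 fold change 0.61, limma adjusted p = 0.00037), Rian from 363 ± 10.1 to 447 ± 37.5 FPKM (0.30, limma adjusted p = 0.0114) and Mirg from 32.5 ± 1.48 to 44.2 ± 1.39 FPKM (0.43, limma adjusted p = 0.00348). The paternally expressed Dlk1 fell by 0.75 on the log2 scale (limma adjusted p = 0.0229), a call lost without clone 1 replicate 2 or WT replicate 1 and without a filter on low values. In clone 2 the paternally expressed Peg3 rose from 17.9 ± 2.03 to 38.2 ± 6.26 FPKM (1.05, limma adjusted p = 0.005) and Ndn from 51.3 ± 3.30 to 89.6 ± 3.75 FPKM (0.79, limma adjusted p = 0.000552). Mest and Magel2 also rose there, by 0.51 (limma adjusted p = 0.00944) and 0.72 (limma adjusted p = 0.0172), and both calls were lost without clone 2 replicate 2. In clone 1, in contrast, Mest fell by 1.13 (limma adjusted p = 0.00046) and Peg3 by 0.55 on the log2 scale (limma adjusted p = 0.0299), and the call of Peg3 was lost without clone 1 replicate 2 or WT replicate 1, 3 or 4 and without a filter on low values. Dlk1 rose by 0.64 in clone 2 (limma adjusted p = 0.0407), a call lost when either clone 2 library or WT replicate 1, 2 or 4 was left out and without a filter on low values. The paternally expressed Sgce fell by 0.48 in clone 1 (limma adjusted p = 0.00381) and by 0.54 in clone 2 (limma adjusted p = 0.0037). Igf2, also paternally expressed, fell in clone 2 by 0.56 on the log2 scale (limma adjusted p = 0.0227). The call of Igf2 was lost without clone 2 replicate 2 or WT replicate 4 and without a filter on low values. For each of these genes both libraries of the clone lay beyond all 4 WT libraries.

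In 2 stretches of chromosome 13 that hold histone genes, medians were above 0 in clone 1. The median log2 fold change was 0.55 for 18 protein-coding genes from 21.72 to 22.04 Mb and 0.61 for 25 from 23.35 to 24.28 Mb, against -0.064 and -0.065 for the other genes of the chromosome, and 3 genes in each stretch passed limma's test as higher and 1 in the first as lower. In clone 2 the medians were -0.22 and -0.21. Over 47 replication-dependent histone genes, the median difference from the WT mean was 1.09 in clone 1 replicate 2, the library with the high share of non-polyadenylated RNA, and 0.16 in clone 1 replicate 1. These stretches and the one on chromosome 4 were the 3 found among 11706 protein-coding genes by a search for at least 10 genes in a row with a running median of 5 genes beyond 0.3, settings chosen after the chromosome 4 stretch was seen.

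A hypothesis on the Y-linked genes was that a single factor, such as the share of cells with a Y chromosome, sets all of them in a line. The ratio of clone 1 to WT was 2.15 for Ddx3y, 2.28 for Eif2s3y and 2.34 for Uty, and the highest was 1.09 times the lowest, as one shared factor predicts for these genes. In clone 2 they stood at 1.54, 0.67 and 2.9 percent of WT, with means of under 1 FPKM, too near 0 for their ratios to be judged. Over the 12 tested genes of chromosome Y with no value of 0, the median log2 fold change was only 0.207 in clone 1 and -0.164 in clone 2. The ratios therefore speak for the genes named here and not for the whole chromosome. Loss of the Y chromosome in clone 2 and in part of the WT cells may account for the named genes. No DNA was measured here.

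Some genes were listed at 0 in single libraries. Peg10, an imprinted gene beside Sgce, stood at 83.5, 59.0, 75.4 and 73.6 FPKM in WT, 30.6 and 26.4 FPKM in clone 1, and was listed at 0 in clone 2 replicate 1 and at 60.1 FPKM in clone 2 replicate 2. Rpl22 was listed at 0 in WT replicate 2 and stood at 672 to 775.6 FPKM in the other 7 libraries. Phf3 was listed at 0 in 4 libraries and Pim2 in clone 1 replicate 2.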
